A study of Mus musculus with 6 samples.

How the data were processed

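Cerebellar granule cells are the small excitatory neurons that fill the inner layer of the cerebellar cortex. Genomic DNA came from nuclei of these cells in a transgenic mouse line (NeuroD1-EGFP-Rpl10a-JP241) in which the Neurod1 locus drives a green fluorescent ribosomal protein. Per the labels' protocols, 4 cerebella (2 from males and 2 from females) were combined before sorting, and nuclei with high green fluorescence and the DNA stain signal of single nuclei were kept. DNA was sheared to fragments of about 200 bp and taken through TrueMethyl-Seq reagents. The series holds 6 libraries in 2 groups. In 3 libraries the DNA was treated with bisulfite directly (MethylC-seq), which leaves both 5-methylcytosine (5mC) and 5-hydroxymethylcytosine (5hmC) unconverted. In the other 3 libraries the DNA was oxidised first (oxBS-seq), so that only 5mC stays unconverted. The difference between both kinds of library estimates 5hmC. The labels do not say whether replicates came from separate pools of animals.

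The deposited table gives 4 values for each RefSeq transcript, per the file headers: 5mC per CG, 5hmC per CG, 5mC per CA and 5hmC per CA, over the transcript's span. Each value is a fraction of cytosines as deposited, from 0 to 1 except in a misplaced row described below, and is printed here in percent. All 4 columns are single values for the whole series, so the libraries were combined by the authors and no column belongs to a library. Per the submitters' processing notes, the genome build was mm10 and the tools included BSMAP 2.87, SAMtools, bedtools and HOMER 4.8, with no role given for any of them. How 5hmC was computed from both kinds of library, how negative differences were treated, which coverage was required and whether sites or reads were averaged are not given in the sources used here. No value was below 0. The depth behind the values is unknown, so no interval, floor or replicate error accompanies any of them. Coordinates are those of the table, 1-based on mm10; 12840 of the 21392 symbols found in the reference gene table had the same start there.

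The table held 31161 transcript rows and 2 blank lines. The last 3 rows (transcripts of Gm2694, Hipk1 and Tunar) were left out, because their columns were misplaced: their CG columns held values close to the CA values of the same genes' other transcripts. For Gm2694 the CG columns read 1.53% and 0.224%, against 1.52% and 0.223% in the CA columns of its other transcript, and the last column of the Tunar row read 123%. The remaining 31158 rows covered 22685 gene symbols, with 31140 rows on the 19 autosomes and 18 on unplaced contigs. Genes of chromosomes X, Y and M were not analysed here, and among the fixed gene lists these include Mecp2. Other listed genes also had no entry. Among them were Cx3cr1, Tmem119, C1qc and Tyrobp, so the microglia list rests on 12 of 16 genes. In 582 rows all 4 values were listed at 0. Of the 3384 spans listed more than once, 525 had differing 5mCG values, by at most 1.77 percentage points.

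Medians, quartiles and correlations were computed over transcript rows, and profiles, gene lists and single genes over symbols, each represented by its longest transcript. Modified CG is 5mCG plus 5hmCG, and modified CA likewise. The 5hmC share of the modified level was computed where modified CG reached 10% (29561 rows) or modified CA reached 1% (15627 rows). The tests were planned for all non-CG cytosines, while the table gives the CA context, which was used in their place. A planned comparison of oxidised with unoxidised libraries was not made, since no column holds a library. Spearman correlations across transcripts describe these pooled libraries and carry no p-value, as genes are not replicates. For the same reason no test of a gene was made.

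Before the data were examined, 24 gene lists were fixed from textbook knowledge: cell types of the cerebellum and neighbouring tissue, forebrain neurons, housekeeping complexes, activity-regulated genes, genes of other organs, imprinted genes, genes of DNA modification and multigene families. Drd1 was found under its older symbol Drd1a. Each list's median was set against the medians of 10000 random lists of the same size, drawn from other symbols within the same of 10 equal groups by gene length. A list at or below the 2.5th or at or above the 97.5th percentile was called outside the random range. This percentile describes the pooled libraries and is not a p-value. With a list, a share or level was given only for at least 5 members. The procedure was tested on simulated data over 22685 genes, with 200 lists for each shift. With no shift of 5hmCG, 4.5% of lists lay above the upper and 1.5% below the lower percentile. A shift of 3 points put 59.5% of lists above the upper percentile, and a shift of 6 points put 97.5% there. The lists were small, and the simulated values were independent between genes. They were normally distributed 5hmCG levels, and each list was set against fewer than 10000 random lists. The simulation therefore does not cover large families, lists of overlapping genes or the 5hmCG share, which was not simulated.

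The genes named in the text follow a rule fixed at the same time. It takes the first 3 genes of each list, the 10 highest and 10 lowest 5hmCG shares, and the 5 highest and 5 lowest values of each column. The ranks run over genes of at least 2 kb with modified CG of at least 10%, a set of 15972 symbols. Predicted and unnamed genes, odorant and pheromone receptors and genes of chromosomes Y and M are left out of them. For 5mCA and 5hmCA the lowest genes are given as a count, since 253 and 546 of these symbols were listed at 0. Genes named for another reason are said to be so. Not every gene that the rule takes is named, so the genes shown for a list may be only part of its first 3. Neurod1 and Rpl10a are also part of the transgene, so their values may mix both copies. Alternatives tried were the size filter, the treatment of zeros, transcripts against symbols, mean against median, the minimum modified level, the correlation measure, adjustment for length and the matching of random lists. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used.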

Results

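The study asked how 5mC and 5hmC are distributed by sequence context in granule cells of the mouse cerebellum, in connection with binding of the methyl-CpG binding protein MeCP2. It measured 3 bisulfite and 3 oxidative bisulfite libraries from sorted granule cell nuclei. The values analysed combine these libraries into levels of 5mC and 5hmC at CG and CA dinucleotides over 31158 transcripts of 22685 genes. No library has values of its own, so no difference described here could be set against a spread between replicates, and the depth is unknown.

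At CG sites the typical gene body was mostly methylated, with a smaller part hydroxymethylated. The median 5mCG over transcripts was 57.4% (interquartile range 40.9% to 68.1%) and the median 5hmCG was 11.9% (9.18% to 15.02%). CA sites carried far less of both marks, with medians of 0.554% 5mCA (0.179% to 1.34%) and 0.396% 5hmCA (0.132% to 0.840%). The balance of the marks differed between the contexts. 5hmC made up a median of 17.96% of modified CG (14.1% to 24.2%) and 39.1% of modified CA (30.1% to 47.0%). Of 10584 genes with both shares, 86.1% had the higher share at CA, and of the 2014 such genes of at least 100 kb, 94.2% did. Among genes of at least 100 kb the lowest 5hmCG listed was 6.36%. The CA levels were skewed: their means were 1.06% for 5mCA and 0.618% for 5hmCA, and weighting by length gave 1.596% and 0.891%.

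Genes that define granule neurons stood apart from all other lists. Over the 14 of 20 measured granule neuron genes with modified CG of at least 10%, 5hmCG made up a median of 48.6% of modified CG, against 17.5% in length-matched random lists (percentile 100), and all 14 exceeded the median of genes of their length. Gabra6, a GABA-A receptor subunit typical of granule cells (chromosome 11, 42306437 to 42321072), held 19.8% 5hmCG and 17.5% 5mCG, a share of 53.1%. Fat2, a large cadherin of granule cell axons (chromosome 11, 55250610 to 55312257), held 30.7% and 30.0%, a share of 50.6%. In Cbln3, which encodes a secreted cerebellin (chromosome 14, 55878920 to 55884256), 5hmCG of 15% exceeded 5mCG of 7.74%, a share of 66.0%. The list of general neuronal and synaptic genes had a median share of 29.2% (percentile 100), and 21 of its 22 genes were above the median for their length. Snap25, a SNARE protein of synaptic vesicle release (chromosome 2, 136713450 to 136782428), had a share of 60.3%. The calcium sensor Syt1 (chromosome 10, 108497650 to 109010975) had 27.04%, and Dlg4, the scaffold PSD-95 (chromosome 11, 70018605 to 70045531), had 25.0%. Both lists lay above the random range also when random lists were matched on modified CG.

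Markers of other cerebellar cells did not share this balance. Purkinje cell genes had a median share of 14.5% against 17.3% in random lists (percentile 2.89), with Pcp2 at 9.57%, carbonic anhydrase-related Car8 at 12.4% and calbindin (Calb1) at 14.5%. This list was inside the random range, but below it with matching on modified CG (percentile 2.28), and near its middle with the mean (38.08). GABAergic interneuron genes had 15.4% (percentile 14.3), and the GABA-synthesising enzymes Gad1 and Gad2 had 14.6% and 13.2%. The medians were 16.98% for astrocyte and Bergmann glia genes, 15.5% for oligodendrocyte genes, 16.2% for microglia genes and 15.3% for endothelial and mural genes, all within the random range. Endothelial and mural genes were below it with the mean in place of the median (percentile 1.42), but near its middle with matching on modified CG (44.13). Among these glial and vascular genes Aqp4, the glial water channel, had 16.7%, and Gfap had 18.9%. Mbp, the myelin basic protein, had 26.4%, and Mog, another myelin protein, had 12.9%. The microglial receptor P2ry12 had 15.8% and Pecam1, an endothelial adhesion molecule, 18.1%. Genes of granule cell progenitors and the cell cycle had a median of 19.5%, in the random range, with the proliferation marker Mki67 at 16.97% and the hedgehog effector Gli1 at 18.03%.

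**Figure D1:**
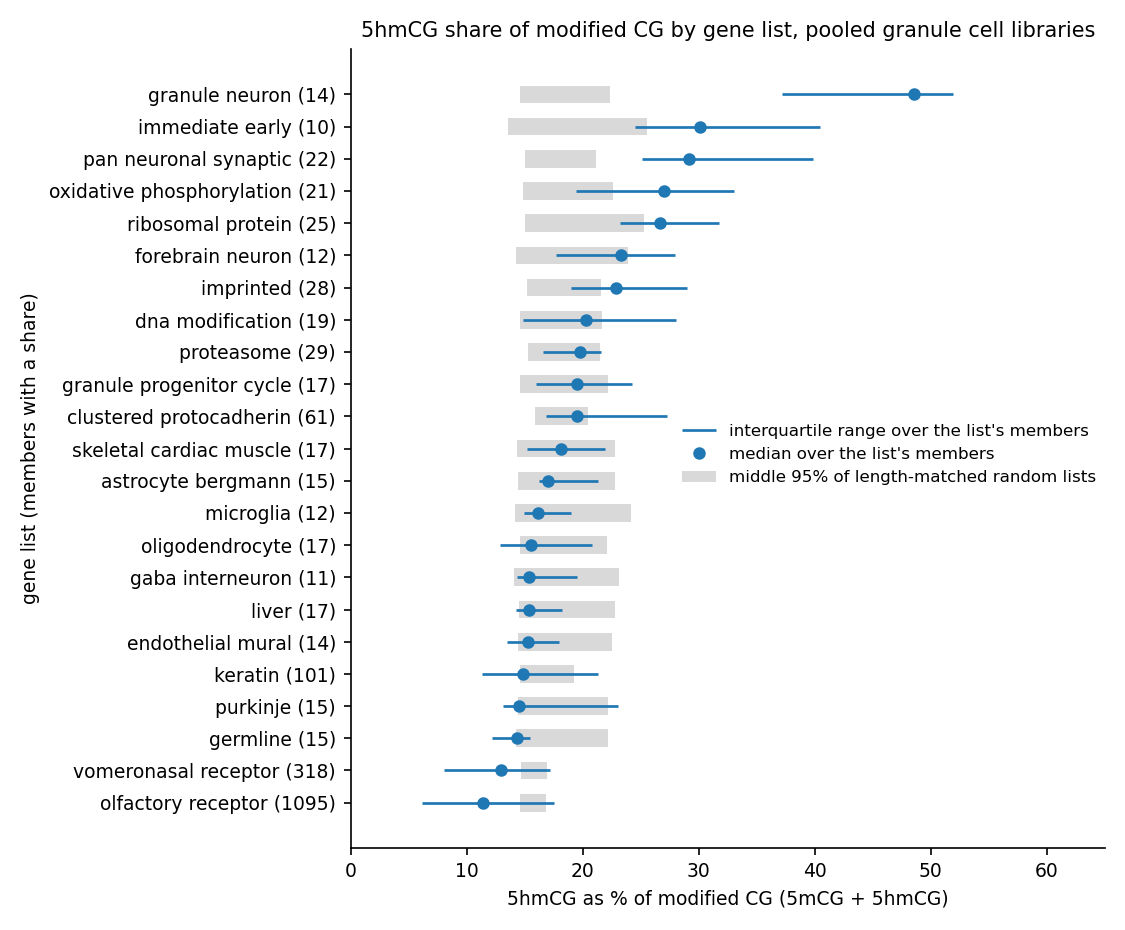
Median 5hmCG share of modified CG (points, %) and interquartile range over members (lines) for each gene list, with the number of members that have a share in brackets. Grey bars give the middle 95% of medians of 10000 length-matched random lists; granule neuron genes sit at 48.6%, right of their bar, and olfactory receptors at 11.4%, left of theirs.

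Immediate early genes and the oxidative phosphorylation and ribosomal protein lists also had high shares. The median was 30.1% for activity-regulated immediate early genes (percentile 99.7), with the transcription factors Fos at 38.2% and Egr1 at 58.8% and the synaptic gene Arc at 53.2%. It was 27.04% for oxidative phosphorylation (percentile 99.99), where the ATP synthase subunit Atp5b reached 65.8% and the complex I subunit Ndufs1 19.4%. It was 26.7% for ribosomal proteins (percentile 99.1; Rpl3 31.8%, Rps6 26.4%). Modified CG was below the random range in immediate early genes and ribosomal proteins, and inside it for oxidative phosphorylation (percentile 3.2). Against random lists matched on modified CG, ribosomal proteins stood at percentile 32.4, immediate early genes at 79.7 and oxidative phosphorylation at 96.6. Ribosomal proteins were also inside the range with the mean in place of the median (percentile 96.45). Imprinted genes had a median of 22.9% (percentile 99.3), and 25 of 28 were above the median for their length, such as Peg3 at 28.2%. Proteasome genes had 19.8%, forebrain neuron genes 23.3% and genes of DNA modification 20.3%, inside the random range. Forebrain neuron genes lay above it (percentile 99.91) only with no minimum modified level, an alternative added after the data were seen. In the DNA modification list the methyltransferase Dnmt3a (chromosome 12, 3806980 to 3914443) had 39.3% and the 5mC oxidase Tet3 (chromosome 6, 83362374 to 83441678) 40.5%.

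The large receptor families lay below the random range. Olfactory receptor genes had a median share of 11.4% (1095 genes) and vomeronasal receptor genes 12.9% (318 genes), both at percentile 0.00. Genes of other tissues lay inside it: germline genes had 14.3% (percentile 2.66), keratins 14.9% (percentile 4.23), liver genes 15.3% (percentile 7.66) and skeletal and cardiac muscle genes 18.2% (percentile 58.1). Keratins lay below it when random lists were matched on modified CG (percentile 0.9) or not matched (0.01), and with only members of at least 2 kb (0.45). Germline genes did so with the mean in place of the median (0.28), and both lists with no minimum modified level, an alternative added after the data were seen (keratins 2.08, germline genes 2.17). In contrast, keratins stood at percentile 32.86 with the mean, and germline genes at 58.61 with matching on modified CG. Single genes of these lists varied. Among liver genes albumin (Alb) had 12.5%, Apob 12.2% and Hnf4a 17.7%. Among muscle genes Acta1 had 44.5%, Ckm 18.97% and the sarcomere protein titin (Ttn) 10.98%. The keratins Krt1, Krt10 and Krt12 had 7.35%, 21.6% and 15.9%. The germline genes Dazl, Ddx4 and Sycp3 had 28.6%, 14.9% and 17.04%. Clustered protocadherins had 19.5%, within the random range. Of the 23 lists with a share, 6 lay above and 2 below the random range, where 1.15 would be outside by chance if members were independent. Some members are not: the spans of Pcdha1, Pcdha10 and Pcdha11 end at the same position and overlap.

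The levels behind these shares differed between the marks. For granule neuron genes, 5mCG was far lower than in random lists (16.3% against 59.0%, percentile 0.00, all 20 genes at or below the median for their length) and 5hmCG was higher (17.1% against 12.2%, percentile 99.99) in 14 of the 20. The other 6 (Zic1, Zic2, Cbln1, Neurod1, Neurod2 and Pax6, named outside the rule) held at most 3.70% 5hmCG and 8.28% modified CG. Modified CG was therefore low as well, at 33.6% against 73.4%. General neuronal genes had the highest list median of 5hmCG, 19.2%, with 43.3% 5mCG against 62.5% in random lists. Hox genes were nearly free of both marks, with medians of 2.10% 5mCG and 1.52% 5hmCG over 39 genes, and Hoxa10 held 3.35% and 1.52%. Several developmental regulators resembled them: Atoh1, the transcription factor of granule cell progenitors, held 0.575% 5mCG and 1.38% 5hmCG, and Foxg1, a forebrain regulator, 1.25% and 0.871%. Forebrain neuron genes as a list had medians of 16.7% 5mCG and 6.35% 5hmCG, and immediate early genes 8.47% and 6.32%, all below the random range. With random lists matched on modified CG, 5hmCG of immediate early genes stood at percentile 88.2, and both levels of forebrain neuron and Hox genes and 5mCG of immediate early genes were inside the range. 5mCG lay above the random range for olfactory receptors (76.2%), germline genes (75.2%), endothelial (70.2%), liver (66.4%), keratin (65.7%) and vomeronasal receptor genes (64.9%). Of these lists only the 2 receptor families stayed above it with matching on modified CG, and liver genes turned to percentile 26.2. For 5mCG, 6 of 24 lists lay above and 11 below the random range, and for 5hmCG 6 above and 6 below. The 5hmCG of olfactory receptors (9.59%) was above length-matched lists (5.80%). It was below lists not matched on length and lists matched on modified CG (percentile 0 for both). Without matching keratins turned as well (percentile 99.6 matched on length, 24.4 not matched). Most of the genes of both lists are short, and other causes of the turn were not tested.

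**Figure D2:**
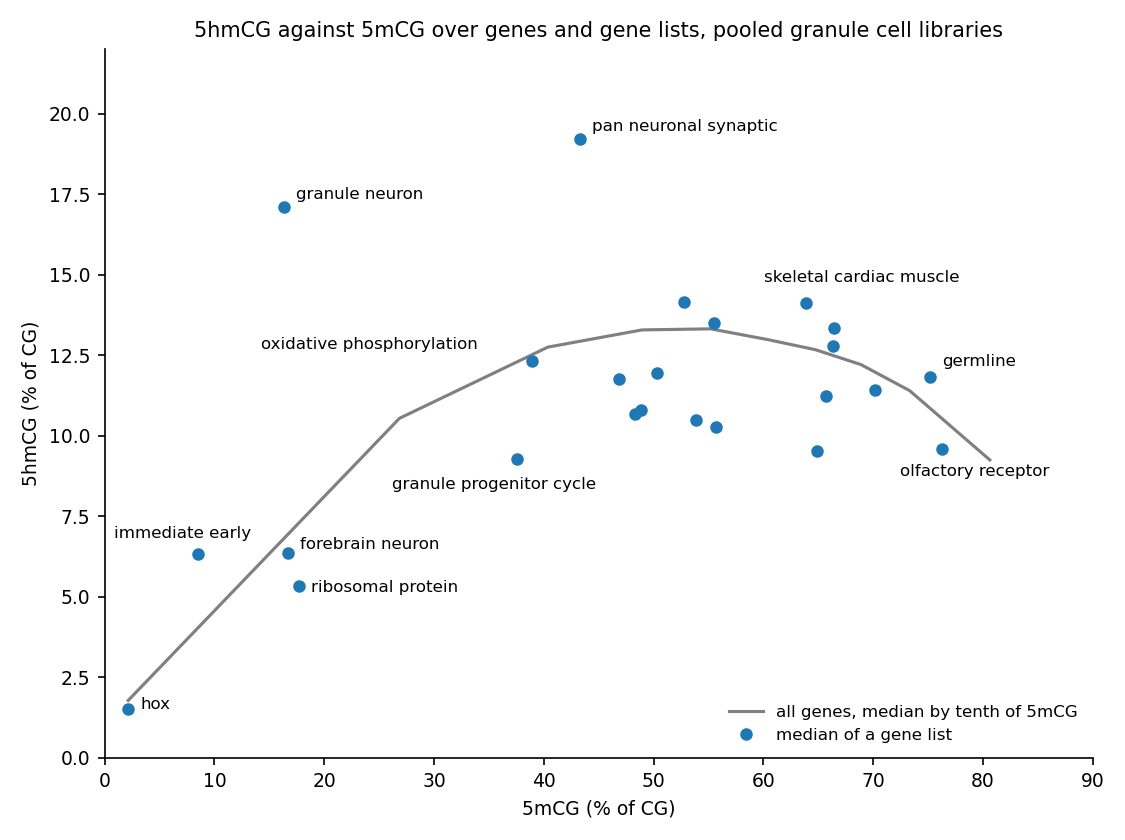
Median 5hmCG (% of CG) against median 5mCG (% of CG) for the 24 gene lists (points), with the median 5hmCG of all genes in each of 10 equal groups by 5mCG (line). Granule neuron genes (16.3% 5mCG, 17.1% 5hmCG) and general neuronal genes (43.3%, 19.2%) lie above the line, and Hox genes lie at its lower left end.

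CA methylation grouped the genes in another way. Proteasome genes had a median 5mCA of 0.171%, oxidative phosphorylation genes 0.199%, ribosomal proteins 0.0545%, Hox genes 0.0182% and vomeronasal receptors 0.0272%, all below the random range. Forebrain neuron genes had 1.27% 5mCA (random 0.555%, percentile 99.1) and 0.966% 5hmCA (percentile 99.7). Keratins had 0.231% 5mCA, above length-matched lists (percentile 98.3) but below lists not matched on length (percentile 0). Granule progenitor and cell cycle genes (0.836%), astrocyte genes (0.794%) and muscle genes (0.732%) had high 5hmCA. Granule neuron genes had 0.465% 5mCA (percentile 6.38) and 0.362% 5hmCA (percentile 13.6), and general neuronal genes had 1.38% (percentile 87.3) and 0.687% (percentile 61.8), all inside the random range. Of 24 lists, 7 were outside the random range for 5mCA and 9 for 5hmCA, where 1.2 would be by chance if members were independent.

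Across transcripts, 5hmCG had almost no overall relation to 5mCG (Spearman rho 0.0597). In the profile over genes, 5hmCG was highest at middle levels of 5mCG. The median 5hmCG was 1.78% in the 10% of genes with the least 5mCG, 13.3% in the group with a median 5mCG of 55.2% and 9.25% in the 10% with the most. The Pearson coefficient was 0.181, and with length held fixed the rank coefficient was -0.0396. 5hmCG was higher in longer genes (rho 0.388, and 0.360 in transcripts of at least 2 kb), with medians of 4.25% in the shortest 10% of genes and 13.9% in the longest 10%. The shortest 10% had a median span of 452 bp. They and the 10% with the least 5mCG had a lower 5hmCG quartile of 0%. Whether a listed 0 is a measured level or a span without calls is not known. 5hmCG was also higher in genes with more 5mCA (rho 0.366), but this coefficient was 0.206 with length held fixed and was 0.169 as a Pearson coefficient. 5mCA itself was tied to length (rho 0.525, and 0.406 in transcripts of at least 2 kb), with a median of 1.43% in the longest 10%. It was also tied to 5hmCA (rho 0.768). These are relations across genes in pooled libraries, and genes are not independent replicates.

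**Figure D3:**
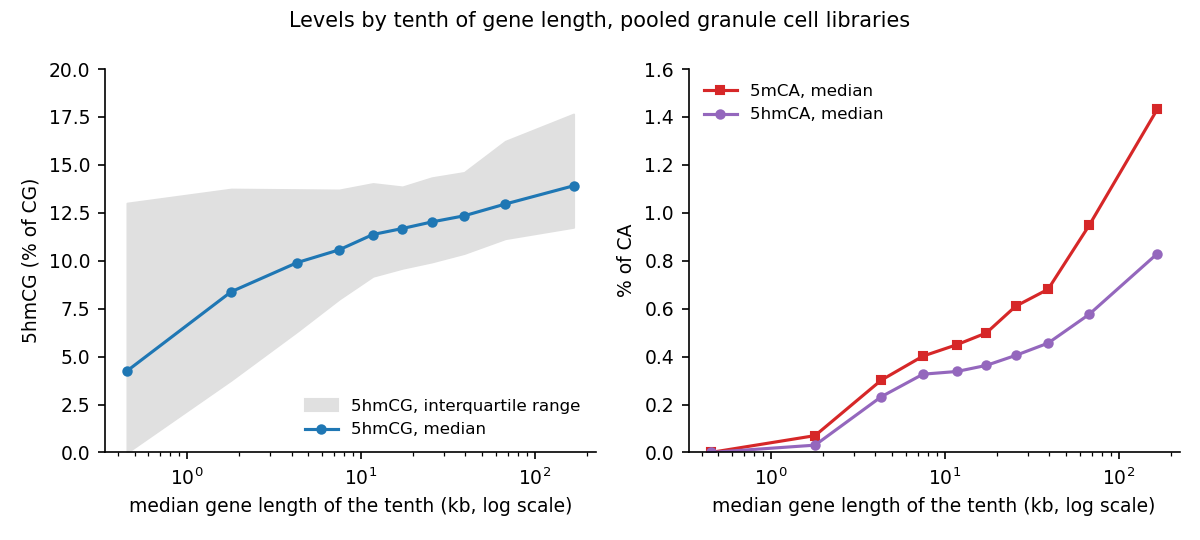
Median 5hmCG (% of CG, left, with the interquartile range over genes in grey) and median 5mCA and 5hmCA (% of CA, right) in 10 equal groups of genes by length, against the group's median length (kb, log axis). 5hmCG goes from 4.25% to 13.9%, 5mCA from 0% to 1.43% and 5hmCA from 0% to 0.830%. The shortest group has a median length of 452 bp and a lower 5hmCG quartile of 0%.

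The 10 genes with the highest 5hmCG share were Lrrc4, a postsynaptic netrin-G ligand (83.9%), Klhl9, a ubiquitin ligase adaptor (83.4%), Ypel4 (79.1%), Rnf112 (77.3%), Phyhip (72.8%), the alpha-tubulin Tuba4a (72.4%), the RNA helicase Ddx5 (72.1%), the heparan sulfate sulfotransferase Hs3st1 (69.6%), the GTPase Diras2 (69.3%) and Abhd8 (67.7%). Their modified CG was low, from 10.5% in Rnf112 to 31.0% in Hs3st1. All ranks in this paragraph run over genes of at least 2 kb with modified CG of at least 10%, with the exclusions given above. In absolute level 5hmCG was highest in Zfhx2os (40.7%), Dnmt3aos (38.9%), Aspdh (36.7%), Ccdc8 (35.9%) and Ankrd23 (33.5%). Dnmt3aos (chromosome 12, 3859293 to 3862244) lies inside the span of Dnmt3a, whose own 5hmCG was 21.9%. At the lowest shares, Esp36, an exocrine gland peptide, and Reg3b, an antimicrobial lectin, were listed at 0 for 5hmCG, with 5mCG of 96.0% and 86.0%. Usp17lc, Esp15, the cornified envelope protein Sprr3, the beta-defensins Defb4, Defb2 and Defb9, H2-M11 and Igfl3 had shares from 1.46% to 3.51%. The ribosomal RNA precursor gene Rn45s had 0.943% 5hmCG and 17.1% 5mCG, and Atpif1 had 1.03% and 10.2%. After Esp36, 5mCG was highest in Sprr3 (93.0%), Scgb3a2 (92.5%), Glycam1 (92.3%) and Akr1c21 (92.2%). Among the ranked genes it was lowest in Klhl9 (2.04%), Lrrc4 (2.17%), Rnf112 (2.39%), Ypel4 (2.89%) and Ddx5 (3.06%). Genes under the 10% minimum, such as Atoh1 (0.575%), could hold less 5mCG. With 5mCG this low, a gene reaches that minimum only with a high 5hmCG share, so both rankings share genes by construction. 5mCA was highest in Zfp872 (49.2%), Lefty2 (32.7%), Serpinb1b (26.5%), Mospd3 (23.2%) and Enpp7 (23.1%). 5hmCA was highest in Wfdc5 (8.74%), Csmd2os (6.24%), Nhlh1 (5.93%), Mcpt8 (5.69%) and the potassium channel Kcna2 (5.59%). Nearly all of these genes are short, and the number of sites behind a value is unknown.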

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

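No paired analysis was possible because no column belongs to a library or replicate number. For the same reason the replicate left out, the block by replicate, and the test of oxidised against unoxidised libraries were not run. The table analysed has no coverage, expression or MeCP2 binding column and no entries on chromosome X, so the coverage minimum, those relations and the comparison of autosomes with X were not run either. Depth is unknown, so what it limits could not be measured. Keeping the misplaced rows, one entry per gene for the correlations, leaving out Neurod1 and Rpl10a and dropping the minimum for list shares were chosen after the data were seen. A level or share counted as moved past 10%, a correlation past 0.1 and a count of lists past 1.5 times, and 77 of 94 settings of the results that answer a comparison moved less. Some of these could hardly move: no value was below 0, autosomes alone left out 18 rows, and the misplaced rows added 3. For lists, this tally compared only the number outside the range. Among settings of single lists, 520 kept their call and 35 came inside the range. Another 21 left it on the same side, 4 left it on the other side and 13 changed side. 5hmCG had a length-weighted mean of 14.6%. 5hmCA was 0.455% in genes of at least 2 kb, 0.479% without zeros, 0.355% with one entry per gene, 0.618% as a mean and 0.891% weighted by length. 5mCA was 0.652%, 0.649%, 1.06% and 1.596% for the same settings without that of one entry per gene. The 5hmCG share was 20.3% as a mean and 20.0% weighted by length. The 5hmCG correlation was 0.181 (Pearson) with 5mCG, and 0.169 (Pearson) and 0.206 (given length) with 5mCA; that with 5mCG crossed 0 in other settings (-0.0396 to 0.181). With random lists matched on modified CG, 6 of 24 lists were outside the range for 5hmCG (from 12) and 6 for 5mCG (from 17), since that matching fixes the sum of both. Under it the percentile changed side for the ribosomal share (32.4), for 5hmCG of immediate early genes (88.2), olfactory receptors (0) and keratins (17.2), for 5mCG of progenitor (95.95), GABAergic (95.5), ribosomal (97.9), liver (26.2) and protocadherin genes (99.6), and for 5mCA of keratins (0.02). Without matching it changed side for 5hmCG of olfactory receptors (0) and keratins (24.4) and for 5mCA of keratins (0), which are short genes; other causes were not tested. The number of lists outside the range for the share was 8, and 7 to 11 in its alternatives.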

Other observations

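The tests reported here were chosen after the results were seen, except the matching of random lists on modified CG, which was planned; the genes named here outside the rule were also chosen after. Some genes departed from their own list. In the Purkinje list, the G protein regulator Rgs8 had a 5hmCG share of 45.2% and the nuclear receptor Rora 29.4%, against the list's 14.5%. Among astrocyte genes, Aldoc had 36.1% and Timp4 31.6%, and among oligodendrocyte genes Cnp had 32.2%, and Gjc2 31.5%. The granule progenitor list held both Bub1, a mitotic checkpoint kinase, at 8.02% and the hedgehog receptor Ptch1 at 34.8%. Barhl1, a transcription factor of granule cells, had 37.2%. Of the muscle genes, Acta1 had 44.5% with modified CG of 33.1%.

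Within the DNA modification list the members also separated. The maintenance methyltransferase Dnmt1 had a share of 13.4% and its cofactor Uhrf1 12.3%, while the de novo enzyme Dnmt3a had 39.3% and Dnmt3b 15.3%. Among the 5mC oxidases, Tet3 had 40.5%, Tet1 17.7% and Tet2 15.97%. The methyl-CpG binding gene Mbd2 had 27.3%, Mbd1 12.2% and Mbd4 11.2%. In the granule list, the transcription factor genes Zic1 and Zic2 were nearly unmodified, with modified CG of 0.0217% and 0.0452%, so neither entered the list's share.

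The granule neuron list combined a high 5hmCG share with low 5mCG. Low modified CG goes with a high share in general, but against lists matched on modified CG the list's 48.6% stood beside 22.6%, at percentile 100, so low modification is not the whole of it. A hypothesis is that 5mCG was converted to 5hmCG at an unchanged total. In the 10 members of at least 20 kb, 5hmCG was 22.8% against 13.3% in random lists and 5mCG 34.0% against 64.0%, so modified CG was 60.4% against 78.4%, at percentile 0. Against these lists, the higher 5hmCG thus did not make up for the lower 5mCG. The low modified CG of the list was known beforehand, and the total of these genes before any conversion is unknown. How much of the 5mCG deficit came by conversion therefore cannot be told. Expression, which the series does not hold in this table, was not tested.

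5hmC made up a larger share of modified CA than of modified CG. More unconverted cytosine in the unoxidised libraries, the same over the genome, would leave 5hmCA in nearly unmodified genes. In 452 genes of at least 2 kb with modified CG under 10%, the median 5hmCA was 0.0752% and the 75th percentile 0.307%. Both lay below the median of 0.440% in all genes of that size, and the low median argues against this explanation. Setting 5hmCA estimates below 0 to 0 once per transcript is also argued against, since 0% of the 2226 genes of at least 100 kb were listed at 0 and the lowest held 0.0502%. Setting negative differences to 0 at each site before averaging may raise the share at any level and stays open, as the table holds no sites. In genes with 4% to 8% modified CA the median share was 36.3%, beside 20.2% for 5hmCG. In the 355 genes above 8% it was 22.2%, beside 20.3%, with quartiles of 9.63% and 36.7%. That class includes the 38 genes with 5mCA of at least 15% described next, whose 5hmCA share was 6.26%. The small excess there is therefore by itself no sure sign that it fades at high modification. In the classes below 8%, which hold none of these 38 genes, the excess did narrow. The median 5hmCA share was 44.4% at 0.25% to 0.5% modified CA and 36.3% at 4% to 8%. The 5hmCG share was 16.3% and 20.2% in the same classes. Below 0.25% modified CA the 5hmCA share was lower again, at 39.2%, with wide quartiles. No biological explanation was tested.

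In 38 genes of at least 2 kb, 5mCA was 15% or more, with a median of 17.95% and a 5hmCA share of 6.26%. Choosing genes by high 5mCA itself favours a low share, since 5mCA is part of the modified level. Misplaced columns as in the last rows of the table would put CA values in the CG columns. The median modified CG of these genes was 73.8%, which argues against this for most of them. It was under 10% in 1 of the 38, to which this argument does not extend. High CA methylation of the surrounding region is argued against too: the genes of at least 2 kb within 200 kb had a median 5mCA of 0.561%, and no neighbour reached more than 10.6%. A short stretch with high CA calls, such as a repeat, may weigh most in short genes, and these genes were short (median 8.81 kb against 19.5 kb, percentile 0.08), though any error that grows in short spans would do the same. In Zeb2os, the transcript that is 1122 bp longer had 17.2% 5mCA and the shorter one 0.355%. Their 5mCG was low, at 4.09% and 2.96%, so this single gene may not stand for the others.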
